A study of Rattus norvegicus with 38 samples.

How the data were processed

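RNA from the livers of 38 male rats was measured, 1 array per animal, on 1-colour whole-genome Agilent arrays with 43379 spots. The groups were CAR control, PB (phenobarbital, 75 mg/kg/day), DDE (the p,p'-isomer of dichlorodiphenyldichloroethylene, a breakdown product of DDT, 100 mg/kg/day), PHE (phenytoin, 225 mg/kg/day), DIC (diclofenac, 15 mg/kg/day), PXR control, CLO (clotrimazole, 50 mg/kg/day), PCN (pregnenolone 16alpha-carbonitrile, 125 mg/kg/day), DES (diethylstilbestrol, 50 mg/kg/day) and DIA (diazepam, 400 mg/kg/day). Each group had n = 4 except DES and DIA with n = 3. Dosing lasted 7 days, the rats were 7 weeks old at the start, and the age given in the labels is 8 weeks. Groups and doses came from the sample labels. For DIC, DES and DIA the labels do not name a control, and the set given by the raw file names was used: CAR control for DIC, PXR control for DES and DIA.

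The deposited raw files hold processed signal intensity per spot, background-subtracted and detrended by Agilent Feature Extraction. Per the labels the version was 10.5.1.1 for all 38 samples. Per the file headers it was 10.5.1.1 for the 20 arrays of the CAR set and 10.7.1.1 for the 18 arrays of the PXR set. The authors also deposited a table of log2 values. Each of its columns matched log2 intensity minus the array's 75th percentile minus the median of the same set's 4 controls, with a median absolute difference of 0.000123 to 0.0167 in the CAR set and 0.000549 to 0.0209 in the PXR set. Against the other set's control the difference was 0.531 to 0.553. In that table, entries that matched no probe numbered 78. The column medians of the authors' log2 table were -0.06, 0.03, 0.02 and -0.01 for CAR control, -0.08, -0.10, -0.04 and 0.06 for PB, -0.10, -0.07, -0.10 and 0.03 for DDE, -0.08, -0.07, -0.10 and 0.09 for PHE, and -0.03, -0.05, 0.18 and 0.14 for DIC. In the PXR set they were -0.02, -0.04, 0.03 and 0.03 for PXR control, 0.02, -0.10, 0.01 and 0.25 for CLO, 0.13, 0.10, 0.02 and 0.04 for PCN, -0.07, -0.10 and -0.19 for DES, and -0.23, -0.23 and -0.14 for DIA.

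Signal over background was used as the measure of depth. In the CAR set 20466 to 25461 probes per array were well above background and the 75th percentile of signal was 173 to 245. In the PXR set the ranges were 22760 to 26550 probes and 223 to 413. Spots set aside by the software numbered 94 to 195 and 72 to 201 per array, no probe was saturated on any array, and the fit of the spike-ins to their known amounts had an R² of 0.996 to 0.998 and 0.993 to 0.998. The headers grade PXR controls 1, 2 and 4, CLO 1 and 4 and PCN 1 as to be evaluated and the others as in range. All were kept. Arrays of the same group correlated at 0.972 to 0.989 across genes, and their median absolute difference was 0.173 to 0.378 log2 over 54 pairs. The number of arrays limits the precision.

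Files were read in R 4.3.3 with data.table version 1.17.8 and jsonlite 2.0.0. Of 41012 probes, the name was updated from a reference name table (assembly GRCr8, names only) by accession for 10835, by current symbol for 5190, by synonym for 3478, by gene identifier for 1087 and by description for 935, and 19487 kept the name in the file. Probe positions are those of the file headers, genome build rn4. The log2 of the processed signal minus the array's 75th percentile was the level of a probe. Probes were kept where well above background on every array of at least 1 group, which left 25114 probes. The brightest probe stood for each gene, giving 21275 genes tested, 11768 of them with a gene symbol, and 3165 with more than 1 kept probe. Cyp1a1 did not pass the filter. A fold is given as "at least" where 1 group lay below background.

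Differences were tested with limma 3.58.1 (a linear model with 1 mean per group over all 38 arrays, contrasts, and moderated variances, median 30.9 residual degrees of freedom), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Errors are standard errors of the contrast. The p-values measure the spread between animals. Each compound was compared with its set's control. The control sets were compared with each other (PXR minus CAR), PHE with PB, and the mean effect of PB, DDE and PHE with that of CLO and PCN. Genes changed in all 5 of these were counted. Pearson correlations of log2 changes across genes were computed for 28 pairs of compounds. Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The method was tested on simulated data made of each gene's mean plus independent normal noise with the gene's own residual spread. With 4 arrays against 4 it recovered 23.9, 70.1 and 89.4% of changes planted at 0.5, 1 and 2 log2, with 2.40% false among 125 calls. With 3 against 4 it recovered 11.9, 68.7 and 93.9%, with 2.52% false among 119. Of 40 simulated lists of 20 genes, the 3 shifted ones were called and 0 others. The simulated noise is independent between genes, so this does not test false calls in lists whose genes vary together.

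The 32 gene lists, written down from textbook knowledge, were target genes of CAR, PXR, AhR, NRF2 and PPARalpha, cholesterol synthesis, fatty acid and triglyceride synthesis, bile acid synthesis and transport, gluconeogenesis and amino acid breakdown, heme synthesis and breakdown, UDP-glucuronosyltransferases and sulfotransferases, glutathione transferases, cell cycle, p53 and growth arrest, acute phase proteins, ER stress, male-biased and female-biased liver genes, oestrogen and growth hormone responsive genes, oncofetal and progenitor genes, circadian clock genes, immediate early genes, markers of hepatocytes, macrophages, neutrophils and monocytes, lymphocytes, stellate cells and fibroblasts, endothelium, cholangiocytes, red blood cells and pancreas, and reference genes. Named genes are a set of preset liver genes, the 10 largest rises and falls per compound (8 for other comparisons) among symbols with no overlap between the arrays of the groups, and up to 4 members of each list with the smallest p. The text gives only part of the genes that meet this rule, a part chosen after the results were seen. Of the others, 1 is not reported here. Comparisons, lists, the naming rule and most alternatives were chosen before the data were examined.

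Alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' values, no filter, only the compared groups in the fit, the mean of a gene's probes, trended and robust variances, slide as a block, rat number as a block, leaving out each array in turn, an adjusted p of 0.01, a 2-fold minimum, the other set's control, the mean of both controls, other members of the activator groups, and camera with the correlation estimated from the data. Quantile normalization after normexp was added after the results were seen. Each slide held 1 set, 3 or 4 groups and at most 1 array of a group, with 5 slides per set. Each group was scanned on 1 of 2 days and 0 days held both control groups, so scan day cannot be separated from the sets and was not used as a block. Rat numbers were checked as pairs: deviations from the group mean correlated at 0.01 on average over 66 pairs with the same number and at -0.00330 over 223 pairs with other numbers, so the main comparisons are unpaired. A gene that was called in neither setting counts as the same when its sign differs. Correlation errors are from leaving out arrays. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.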

Results

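The arrays covered 8 compounds and 2 control groups in 2 sets that share no slide. The CAR set (CAR control, PB, DDE, PHE and DIC, n = 4 each) had 20466 to 25461 probes per array well above background. The PXR set (PXR control, CLO and PCN, n = 4 each, DES and DIA, n = 3 each) had 22760 to 26550. Changes below are log2 differences from the set's own control with their standard error, or folds, and "changed" means an adjusted p below 0.05 over 21275 genes (21272 for DIC). Within-slide values compare 1 array with 1.

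**Figure D1:**
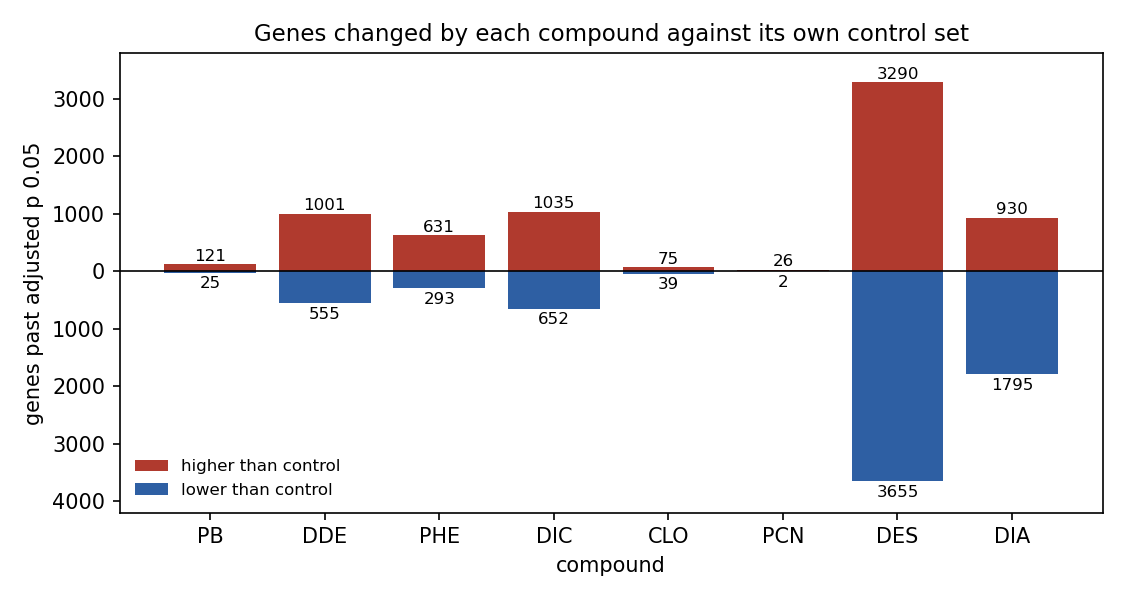
Genes higher and lower than the set's own control at an adjusted p below 0.05, for each compound. DES changed most (3290 higher and 3655 lower) and PCN least (26 and 2).

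What did PB change? The clearest rises were in the cytochromes P450 of the 2B family, the classical phenobarbital-inducible enzymes of rat liver. Cyp2b1 (chromosome 1, probe at 81289963 to 81290022, genome build rn4) rose 140-fold (7.13 ± 0.31 log2, adjusted p = 4.32e-17) and Cyp2b2 (chromosome 1, 81359275 to 81359334) rose 64.3-fold (6.01 ± 0.24, adjusted p = 2.54e-18), n = 4 against 4. Cyp2b12 and Cyp2b15 rose 85.0-fold and 41.4-fold. The sequences of this family are close to identical, so how much each probe reads of its neighbours is uncertain. The efflux transporter gene Abcc3 (chromosome 10, 82986913 to 82986972) rose 42.6-fold and the glutamate receptor subunit gene Grin2c (chromosome 10, 105323249 to 105323308) 20.6-fold, both above background on only 2 of 4 control arrays. The glucuronosyltransferase gene Ugt2b1 (chromosome 14, 22650838 to 22650897) rose 18.2-fold, the carboxylesterase gene Ces2c (chromosome 1, 267892271 to 267892585) 14.0-fold and the stress gene Gadd45b 8.88-fold (3.15 ± 0.42). Cyp3a23-3a1 (chromosome 12, 9567010 to 9567069), a main PXR target, rose 4.84-fold (2.28 ± 0.27, adjusted p = 1.41e-06).

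Other PB rises were in conjugation and redox enzymes. Gstm3 rose 7.06-fold, Aldh1a1 5.27-fold, Ephx1 4.60-fold (2.20 ± 0.24) and Akr7a3 4.42-fold (2.15 ± 0.37). Gstm1 (2.38-fold, adjusted p = 0.000236) and Mgst2 (2.12-fold, adjusted p = 7.65e-06) rose too, but with normexp their adjusted p reached 0.131, the highest over the alternatives. Among falls, Cep295 dropped by 1.75 log2 (3.37-fold lower, adjusted p = 0.0137). That call ended without CAR control 5 (0.0502) and without PB 5 (0.0547), and its adjusted p ran from 0.00474 to 0.849 over the alternatives. Cyp3a2 rose 2.80-fold (1.49 ± 0.31, adjusted p = 0.0143), lost in 6 of 17 alternatives (up to 0.210, with normexp). The reductase gene Por did not pass (1.14 ± 0.29, adjusted p = 0.0534), though it did with rat number as a block (0.0418, the lowest over the alternatives, up to 0.769) and with trended variances (0.0459). Nor did Alas1 (1.00 ± 0.38), Cyp3a9 (1.71 ± 0.48), Cyp1a2, Cyp4a1 (-0.12 ± 0.29), Cyp7a1 (-2.01 ± 0.89), Ccnd1 or Mki67 (0.13 ± 0.39, adjusted p = 0.958).

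By the fixed lists, 12 of 22 CAR target genes rose after PB (15 adjusted over the list alone) and 0 fell, Cyp2b1, Ugt2b1 and Ephx1 among them (median 1.51 log2, camera adjusted p = 6.42e-47, 1.55 with slide as a block). Of 19 PXR target genes 7 rose (12 rose and 1 fell over the list alone), median 1.14, 1.16 with slide as a block, camera adjusted p = 2.10e-24. Of 18 glutathione transferases 6 rose, of 20 glucuronosyl- and sulfotransferases 3 and of 20 NRF2 target genes 4 (9, 7 and 6 over each list alone), with medians of 0.41, 0.42 and 0.46. The camera call of the NRF2 list (adjusted p = 3.10e-09) was not kept, adjusted p = 0.0518 with an estimated correlation. The 36 cell cycle genes had a median of 0.44 (camera adjusted p = 9.94e-07; adjusted p = 0.208 with an estimated correlation), yet 0 of them passed singly, as with Tyms (0.65 ± 0.17). Hepatocyte markers shifted by -0.20 (camera adjusted p = 4.28e-07, 0.0811 with an estimated correlation).

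PB changed 146 genes, 121 higher and 25 lower (82.9% higher), 72 of them by at least 2-fold. Without CAR control 1 the count was 91, without CAR control 3 it was 88, without CAR control 4 it was 94 and without PB 5 it was 74. With slide as a block it was 108. Within 3 slides Cyp2b1 rose by 6.82 to 7.69 log2 and Cyp3a23-3a1 by 1.30 to 3.40, and the CAR target list by 1.64 to 1.85.

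**Figure D2:**
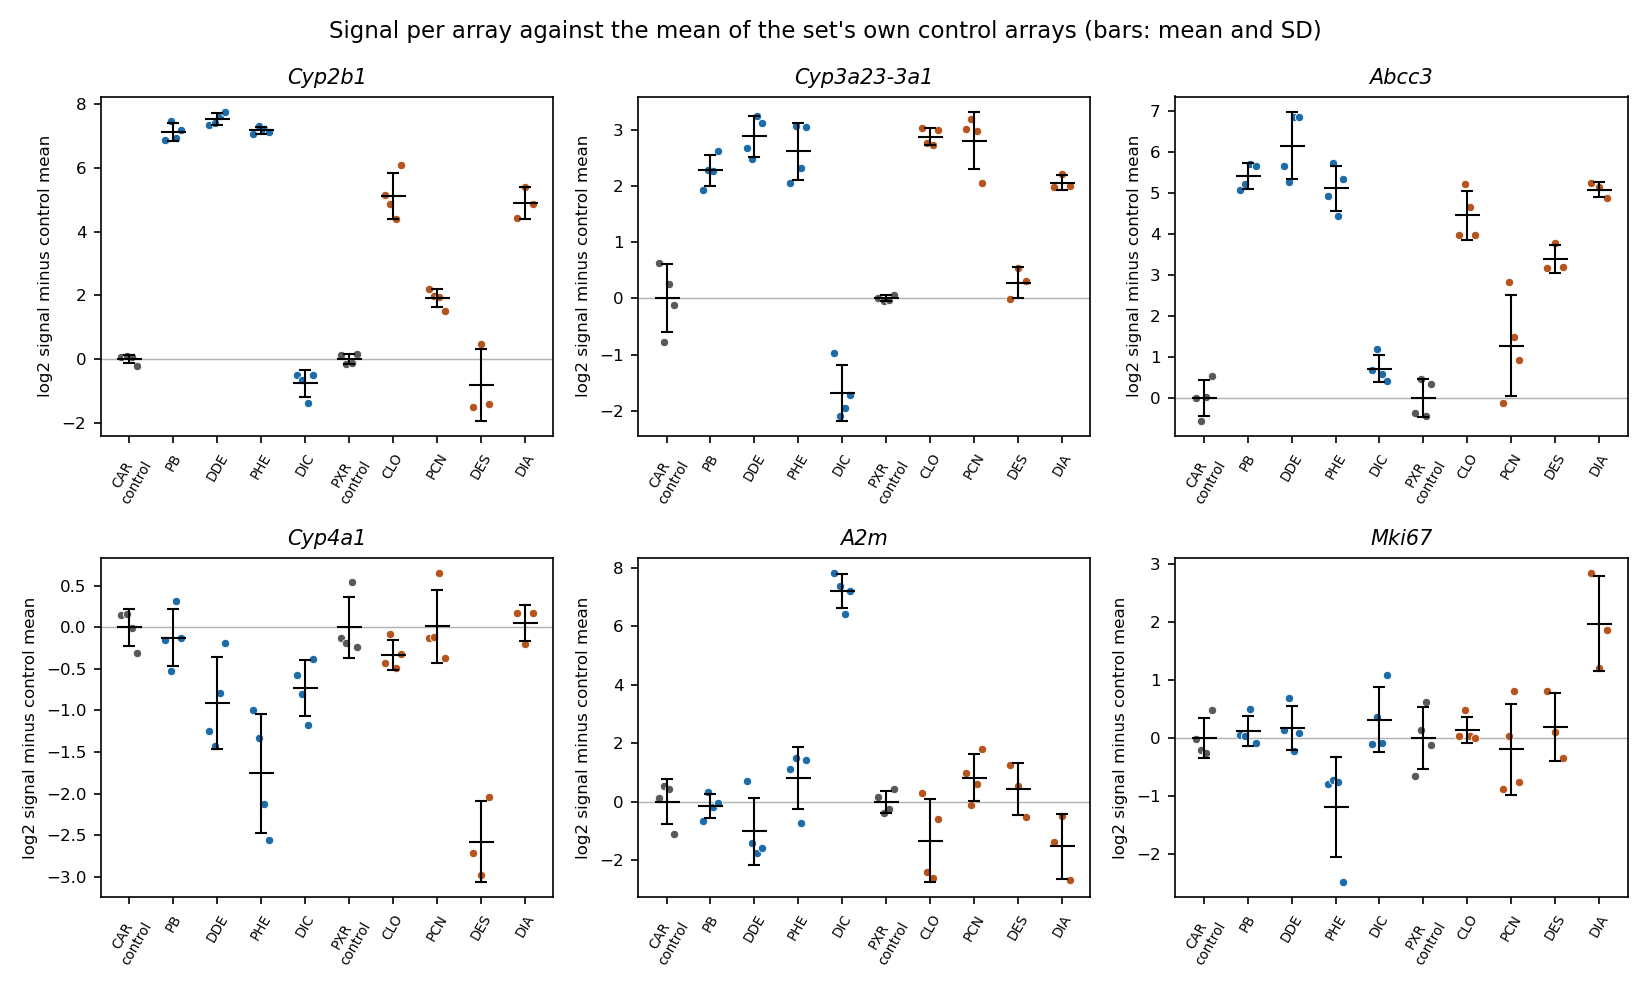
Log2 signal of 6 genes on each array minus the mean of the set's own controls, with group mean and standard deviation as bars (blue CAR set, orange PXR set, grey controls). Cyp2b1 rises in 6 groups, Cyp3a23-3a1 rises in 6 and falls after DIC, A2m rises after DIC, and Mki67 rises after DIA.

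What did DDE, the persistent DDT metabolite, change? The same drug metabolism genes led. Cyp2b1 rose 186-fold (7.54 ± 0.31 log2, adjusted p = 8.29e-18), Cyp2b12 117-fold and Cyp2b2 66.7-fold (6.06 ± 0.24), n = 4 against 4. Grin2c rose 132-fold and Abcc3 71.4-fold, each above background on 2 of 4 control arrays, and the stress gene Ddit4l 43.4-fold, above background on 1. The aldehyde dehydrogenase gene Aldh1a7 rose by 10.18 ± 2.56 log2 (adjusted p = 0.0122), and was above background on 2 of 4 control arrays. Ugt2b1 rose 24.3-fold, Ces2c 23.0-fold, Gadd45b 12.6-fold and Cyp3a23-3a1 7.35-fold (2.88 ± 0.27, adjusted p = 6.42e-09). Por, the electron donor of these cytochromes, rose 3.45-fold (1.78 ± 0.29, adjusted p = 0.000129) and Cyp3a2 3.17-fold.

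Redox and conjugation enzymes rose after DDE as well: Akr7a3 9.06-fold, Gstm3 7.93-fold, Ephx1 7.53-fold, Ugt1a6 5.34-fold (2.42 ± 0.27), the quinone reductase gene Nqo1 3.77-fold (1.92 ± 0.38, adjusted p = 0.00138), Gsr 3.40-fold and Mgst2 2.90-fold. The calcineurin regulator gene Rcan1 fell by 1.63 ± 0.40 log2 (3.10-fold lower, adjusted p = 0.00966). The ERK phosphatase gene Dusp6 was 3.09-fold lower (adjusted p = 0.000794) and the transcription factor gene Onecut1 11.6-fold lower (adjusted p = 0.0102), but with only the compared groups their adjusted p was 0.0589 and 0.0515, the highest over the alternatives. The apolipoprotein gene Apoc3 (-0.87 ± 0.18, adjusted p = 0.00178) was lost there (0.125) and with normexp (0.122), and the transthyretin gene Ttr (-0.66 ± 0.14, adjusted p = 0.00356) too (0.103 and 0.171). Alas1 (1.46 ± 0.38, adjusted p = 0.0156), Cyp3a9 (1.60 ± 0.48, adjusted p = 0.0375) and Cyp4a1 (-0.91 ± 0.29, adjusted p = 0.0483) passed in the main setting but were lost in 4, 7 and 12 of 17 alternatives (up to 0.130, 0.141 and 0.282). Cyp1a2 (0.25 ± 0.49), Cyp7a1, Ccnd1 and Mki67 (0.17 ± 0.39) did not pass, and the probes of Mki67 differed in sign.

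Of 22 CAR target genes 18 rose and 2 fell after DDE (18 and 3 over the list alone), median 1.71 log2 (camera adjusted p = 4.45e-32, 1.76 with slide as a block). Of 19 PXR target genes 14 rose and 1 fell (15 and 1), median 1.60, of 20 NRF2 target genes 11 rose (14), median 1.00, of 18 glutathione transferases 10 rose (11), median 0.62, and of 20 glucuronosyl- and sulfotransferases 10 rose and 1 fell (11 and 2), median 0.72. The heme list had 3 of 12 higher (5), Fech among them, median 0.38 (camera adjusted p = 4.35e-05). Fech itself (1.88-fold, adjusted p = 0.00212) had an adjusted p of up to 0.124 over the alternatives, with normexp. Acute phase genes went the other way: 6 of 21 fell (1 rose and 12 fell over the list alone), median -0.40 (camera adjusted p = 9.17e-06; adjusted p = 0.0825 with an estimated correlation). Of 17 hepatocyte markers 6 fell (10), median -0.30 (camera adjusted p = 1.41e-06, 0.0825 with an estimated correlation).

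Smaller camera calls after DDE, all lost with an estimated correlation, were AhR targets (median 0.25, adjusted p = 0.0278; adjusted p = 0.0725 with an estimated correlation), where Nqo1 and Ugt1a6 rose, and immediate early genes (median -1.10, adjusted p = 0.00479; adjusted p = 0.488 with an estimated correlation), where 0 of 14 passed singly. Oestrogen and growth hormone responsive genes had 2 of 17 lower (median -0.31, adjusted p = 0.0277, 0.148 with an estimated correlation). DDE changed 1556 genes, 1001 higher and 555 lower (64.3% higher), 339 by at least 2-fold. The count was 967 without DDE 4, 603 without DDE 5, and 1588 with slide as a block. Within 3 slides Cyp2b1 rose by 7.27 to 7.71 log2, Cyp3a23-3a1 by 2.61 to 3.45, and the NRF2 list by 0.88 to 1.35.

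What did PHE, a hydantoin anticonvulsant, change? Again the 2B cytochromes rose. Cyp2b1 was 146-fold higher (7.19 ± 0.31 log2, adjusted p = 3.22e-17), Cyp2b12 85.8-fold, Cyp2b2 63.5-fold, Cyp2b15 44.1-fold and Cyp2b21 7.82-fold (2.97 ± 0.18), n = 4 against 4. Grin2c rose 37.2-fold, Abcc3 34.5-fold (5.11 ± 0.42), Ugt2b1 20.9-fold, Ces2c 18-fold and Ces2a 7.67-fold. Cyp3a23-3a1 rose 6.12-fold (2.61 ± 0.27, adjusted p = 6.29e-08) and Cyp3a2 3.54-fold (1.82 ± 0.31, adjusted p = 0.000632). Gstm3, Ephx1, Ugt1a6, Mgst2 and Gsr rose 6.08, 5.39, 3.52, 2.84 and 2.69-fold. Por rose 2.90-fold (adjusted p = 0.00174) and Gadd45b 3.66-fold (adjusted p = 0.00964), calls lost with normexp (0.0889 and 0.0970, the highest over the alternatives). Cyp3a9 rose 3.98-fold (adjusted p = 0.0154), lost in 3 of 17 alternatives (up to 0.115, with normexp).

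Among the falls after PHE were genes of fatty acid oxidation. The fatty acid hydroxylase gene Cyp4a1 (chromosome 5, 135915621 to 135915680), a marker of PPARalpha activity, was 3.37-fold lower (-1.75 ± 0.29, adjusted p = 0.000373, range over alternatives 7.24e-05 to 0.0540, the highest with only the compared groups). The mitochondrial genes Eci1 (-0.81 ± 0.18, adjusted p = 0.00943), Acadm (-0.46 ± 0.10, adjusted p = 0.00855) and Hadha (-0.46 ± 0.11, adjusted p = 0.0136) fell less. Each call ended without PHE 4 (0.0652, 0.0594 and 0.0519), and with normexp (0.118, 0.149 and 0.265) and only the compared groups (0.152, 0.120 and 0.0732). The mitochondrial carrier gene Slc25a30 was 5.74-fold lower (-2.52 ± 0.54, adjusted p = 0.00607) and the tight junction gene Cldn1 2.49-fold lower (-1.32 ± 0.29, adjusted p = 0.00801). Rb1 was 2.21-fold lower (adjusted p = 0.00319), but its adjusted p was 0.142 with the mean of its probes, the highest over the alternatives. Cyp1a2, Cyp7a1 (0.25 ± 0.89), Alas1, Ccnd1 and Mki67 (-1.19 ± 0.39, adjusted p = 0.0686) did not pass.

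Of 22 CAR target genes 14 rose after PHE (16 rose and 3 fell over the list alone), median 1.62 log2, 1.65 with slide as a block (camera adjusted p = 3.34e-26). Of 19 PXR targets 12 rose (12 and 1), median 1.48, of 18 glutathione transferases 11 (13), median 0.71, and of 20 glucuronosyl- and sulfotransferases 10 (12 and 1), median 0.62. The heme list had 3 of 12 higher (5), Blvrb among them, median 0.46 (camera adjusted p = 0.000212, 0.304 with normexp). Blvrb alone (1.76-fold, adjusted p = 0.000472) ranged from 0.000205 to 0.371 over the alternatives. NRF2 targets had 6 of 20 higher (9), median 0.56 (camera adjusted p = 5.28e-08, 0.0715 with an estimated correlation). Of 31 PPARalpha targets 8 fell (1 rose and 22 fell over the list alone), median -0.52, camera adjusted p = 1.95e-11 (0.0715 with an estimated correlation). Cholesterol synthesis genes had a median of 0.51 with 1 of 25 higher (7), camera adjusted p = 0.000396, 0.139 with normexp (adjusted p = 0.496 with an estimated correlation). Reference genes had 3 of 12 higher, median 0.16 (camera adjusted p = 0.0215, 0.158 with quantile normalization and 0.370 with normexp; adjusted p = 0.0808 with an estimated correlation). The acute phase list differed in sign between its median (-0.01) and its mean (0.10), adjusted p = 0.908.

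PHE changed 924 genes, 631 higher and 293 lower (68.3% higher, against 56.5% with quantile normalization), 180 by at least 2-fold. Counts were 610, 485 and 605 without CAR control 1, 3 and 5, 567 without PHE 2 and 348 without PHE 4. With slide as a block the count was 1258. Normexp moved the median of all genes to 0.14 log2. Within 3 slides Cyp2b1 rose by 7.05 to 7.26 log2 and Cyp3a23-3a1 by 2.05 to 3.82, and the PPARalpha list ran from -0.98 to -0.09.

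What did DIC, a non-steroidal anti-inflammatory drug, change? Acute phase and neutrophil genes rose. A2m (chromosome 4, 158153318 to 158153377), whose product alpha-2-macroglobulin is the main acute phase protein of the rat, rose 148-fold (7.21 ± 0.61 log2, adjusted p = 2.42e-09), n = 4 against 4. The calgranulin genes S100a8 and S100a9 of neutrophils rose 13.4-fold (3.75 ± 0.44) and 11.5-fold (3.52 ± 0.38), Wfdc21 16.3-fold and Rfx2 12.7-fold. Orm1 rose 8.43-fold (3.07 ± 0.28, adjusted p = 1.30e-08), Lbp, which binds bacterial lipopolysaccharide, 5.87-fold (2.55 ± 0.21), Itih4 2.80-fold, Pcolce 7.84-fold and the lipoxygenase gene Alox15 7.05-fold (2.82 ± 0.46). Fgb (1.52-fold, adjusted p = 0.00122) and Serpina1 (1.48-fold, adjusted p = 0.00154) also rose, calls lost with quantile normalization (0.186 and 0.0577) and with normexp (0.261 and 0.364, the highest over the alternatives).

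Falls after DIC took in several enzymes. Hsd11b2, which inactivates corticosterone, was 9.81-fold lower (-3.29 ± 0.55, adjusted p = 0.000278), the methyltransferase gene Inmt 6.32-fold lower (-2.66 ± 0.56, adjusted p = 0.00370) and Dnah9 7.47-fold lower, measured above background on 3 of 4 DIC arrays. Cyp3a23-3a1 was 3.21-fold lower (-1.68 ± 0.27, adjusted p = 0.000181), opposite to the other CAR-set compounds. Cyp3a9 was 3.76-fold lower (adjusted p = 0.0142), a call that ended without CAR control 1 (0.0527) and DIC 5 (0.0667) and reached 0.0984 with normexp, the highest over the alternatives. Cyp2b1 (-0.75 ± 0.31, adjusted p = 0.129), Cyp2b2 (-0.71 ± 0.23, adjusted p = 0.0576, 0.0481 with quantile normalization and 0.0494 with trended variances), Abcc3 (0.72), Cyp4a1 (-0.73), Cyp3a2, Cyp1a2, Cyp7a1, Por, Alas1, Gadd45b, Ccnd1 (-1.57 ± 0.53) and Mki67 (0.32 ± 0.39) did not pass. Ccnd1 did pass without CAR control 1 (0.0232) or DIC 2 (0.0479) and with the mean of its probes (0.0381).

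Of 21 acute phase genes 12 rose and 1 fell after DIC (17 and 1 over the list alone), median 0.59 log2, 0.58 with slide as a block (camera adjusted p = 1.50e-16, 0.00397 with an estimated correlation). Of 6 neutrophil and monocyte markers 4 rose, S100a8 and S100a9 among them, median 0.75 (camera adjusted p = 8.20e-05). Macrophage markers had 2 of 12 higher (8), median 0.52 (camera adjusted p = 0.000116, 0.440 with an estimated correlation). Endothelial markers had 4 of 13 higher (8), median 0.47 (camera adjusted p = 0.000226; adjusted p = 0.102 with an estimated correlation): Stab2 rose 2.15-fold (adjusted p = 0.00262), Tie1 1.96-fold (adjusted p = 0.00436, 0.0962 with only the compared groups and 0.351 with normexp, the highest over the alternatives). Vwf rose 1.82-fold (adjusted p = 0.000225) by its brightest probe, but its probes differed in sign and their mean gave 0.306, the highest over the alternatives. Lymphocyte markers had 1 of 9 higher (2), median 0.44 (camera adjusted p = 0.0370, 0.565 with an estimated correlation). Red blood cell markers had 2 of 8 higher (5), median 1.02, 0.78 with slide as a block (camera adjusted p = 0.000830, 0.367 with an estimated correlation). Hepatocyte markers had 4 of 17 higher, median 0.19 (camera adjusted p = 0.00272, 0.917 with quantile normalization and 0.0989 with normexp; adjusted p = 0.454 with an estimated correlation).

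Camera also called lower lists after DIC, each lost with an estimated correlation. Of 31 PPARalpha targets 8 fell (14), median -0.41 (camera adjusted p = 1.42e-09; adjusted p = 0.216 with an estimated correlation), with Acadm at -0.54 ± 0.10 (adjusted p = 0.00142, 0.325 with normexp, the highest over the alternatives). Of 19 PXR targets 4 fell (6), median -0.38 (camera adjusted p = 0.000773, 0.342 with an estimated correlation). Male-biased genes had 4 of 17 lower (5), median -0.27 (camera adjusted p = 0.00272, 0.412 with an estimated correlation). Of 22 CAR targets 1 fell and 0 rose, median -0.17. DIC changed 1687 genes, 1035 higher and 652 lower (61.4% higher, against 50.9% with quantile normalization), 324 by at least 2-fold. Counts were 882 and 868 without CAR control 3 and 4, 930 without DIC 3, 771 without DIC 5, and 1595 with slide as a block. Within 3 slides the acute phase list rose by 0.40 to 0.52 log2, the neutrophil list by 0.51 to 1.26, and Cyp3a23-3a1 ran from -2.35 to -0.86.

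**Figure D3:**
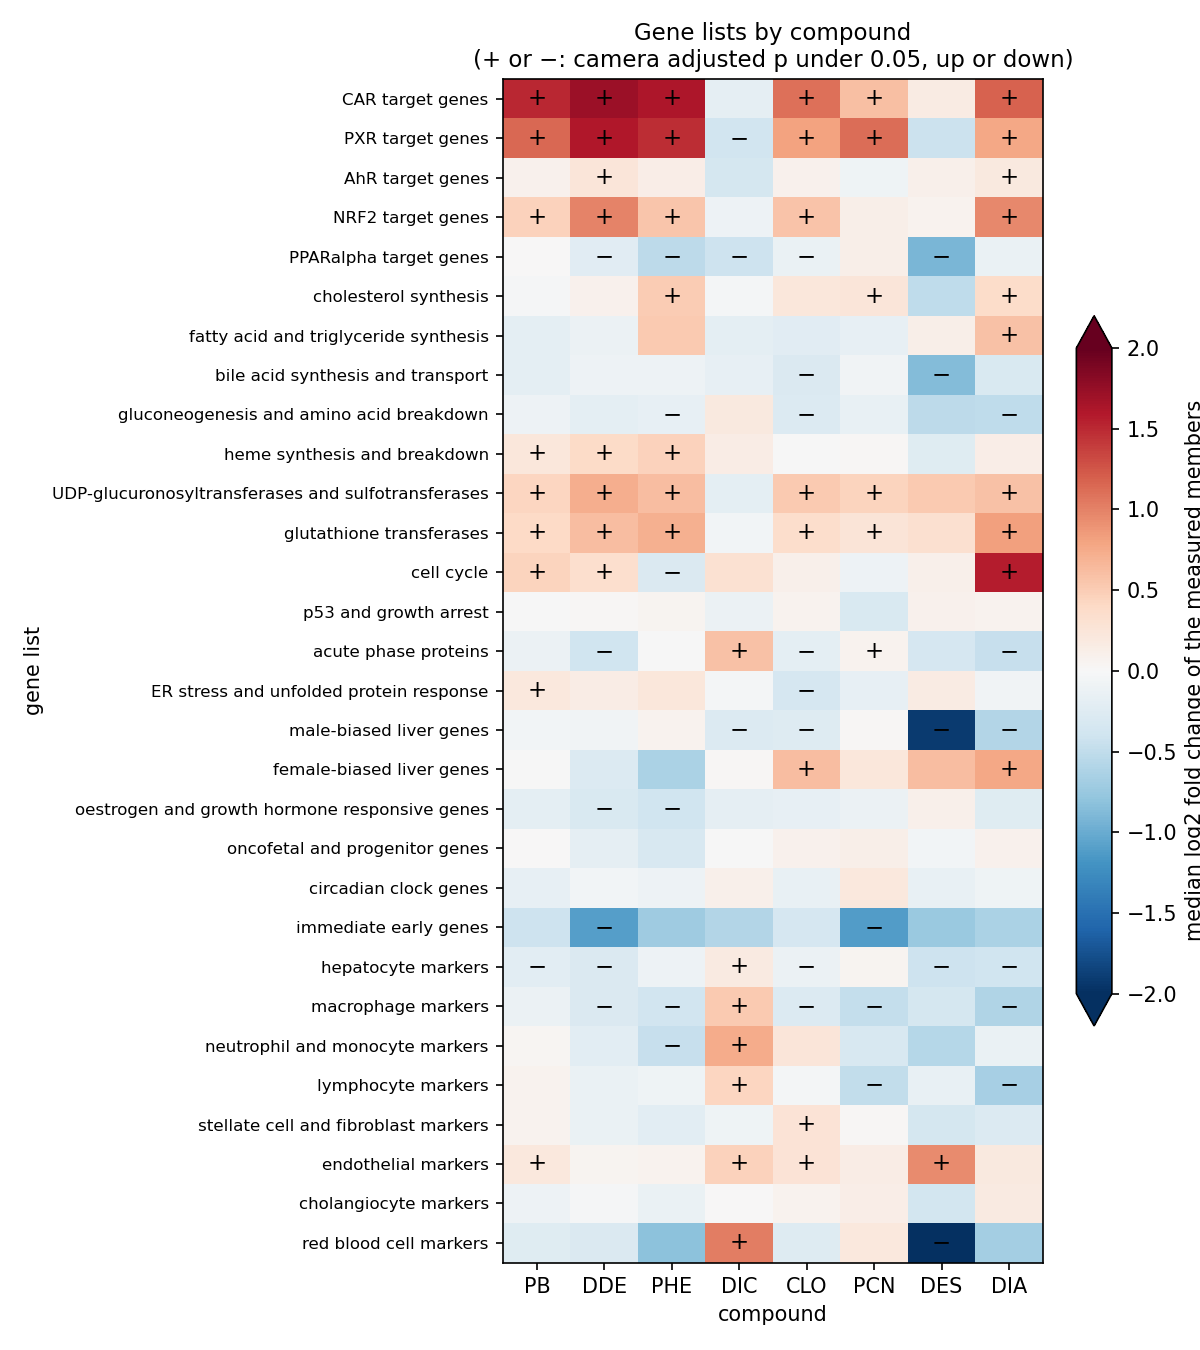
Median log2 change of 30 gene lists (vertical) after each of 8 compounds (horizontal), red higher and blue lower. A sign marks a camera adjusted p below 0.05. CAR target genes are higher after PB, DDE, PHE, CLO, PCN and DIA, cell cycle genes are highest after DIA (1.57), and male-biased genes and red cell markers are low after DES (-1.91 and -2.12).

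What did CLO, an azole antifungal, change? Grin2c rose 35.4-fold (5.14 ± 0.47 log2, adjusted p = 1.54e-08), Cyp2b1 35.1-fold (5.13 ± 0.31, adjusted p = 7.76e-13), Abcc3 22.0-fold and Cyp2b2 18-fold (4.17 ± 0.24), n = 4 against 4 PXR controls. Ugt2b1 rose 12-fold, Ces2c 10.4-fold, Cyp2b15 9.87-fold, Cyp2b12 8.46-fold, Ces2a 7.01-fold, Gstm3 3.23-fold and Ephx1 2.55-fold (1.35 ± 0.24, adjusted p = 0.00248). Cyp3a23-3a1 rose 7.34-fold (2.88 ± 0.27, adjusted p = 1.56e-08). Ugt2a1, below background in controls, rose at least 2.95-fold (adjusted p = 0.000101), but its adjusted p was 1.00 with normexp, the highest over the alternatives. Mgst2 (1.96-fold, adjusted p = 8.26e-05) and Gsta3 (2.14-fold, adjusted p = 0.00453) were lost there too (0.0961 and 0.322, the highest over the alternatives). Cyp3a9 (4.44-fold, adjusted p = 0.0289) was lost in 8 of 17 alternatives (up to 0.138, without PXR control 2). Peroxisomal Hao1 (-0.81 ± 0.15, adjusted p = 0.00595) fell in the main setting, but not with only the compared groups (0.0690) or normexp (0.216, the highest over the alternatives). The potassium channel gene Kcnh1 was 5.74-fold lower (adjusted p = 0.0114, range 0.00247 to 0.0742), a call that ended without PXR control 1 (0.0583), PXR control 2 (0.0622) or CLO 2 (0.0742) and with only the compared groups (0.0677). Cyp3a2 (0.48), Cyp1a2, Cyp4a1 (-0.33 ± 0.29), Cyp7a1, Por (0.35 ± 0.29), Alas1, Gadd45b, Ccnd1 and Mki67 (0.14 ± 0.39) did not pass.

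Of 22 CAR target genes 9 rose after CLO and 0 fell (13 over the list alone), median 1.11 log2, 1.099 with slide as a block (camera adjusted p = 9.39e-28). Of 19 PXR targets 6 rose (10 rose and 1 fell over the list alone), median 0.81, of 20 glucuronosyl- and sulfotransferases 5 (9), median 0.53, of 18 glutathione transferases 3 (8), median 0.35, and of 20 NRF2 targets 2 (10), median 0.57. Bile acid genes had 0 of 18 past the threshold over all genes (4 fell over the list alone), median -0.28 (camera adjusted p = 0.000474, 0.0265 with an estimated correlation), as with Abcb4 (-0.50 ± 0.16) and Hsd3b7 (-0.52 ± 0.16). The ER stress list (median -0.34, camera adjusted p = 0.000258; adjusted p = 0.395 with an estimated correlation), gluconeogenesis (-0.27, camera adjusted p = 0.000111; adjusted p = 0.223 with an estimated correlation) and stellate markers (0.27, camera adjusted p = 0.0338; adjusted p = 0.501 with an estimated correlation) had 0 genes past the threshold. So did endothelial markers (0.28, camera adjusted p = 0.000483, 0.0725 with an estimated correlation). CLO changed 114 genes, 75 higher and 39 lower (65.8% higher), 61 by at least 2-fold. Counts were 67, 61, 75 and 75 without PXR control 1, 2, 3 and 4, 59 without CLO 2 and 70 without CLO 3, and 83 with slide as a block. Within 3 slides Cyp2b1 rose by 4.73 to 6.27 log2, Cyp3a23-3a1 by 2.69 to 3.04, and the CAR target list by 0.65 to 1.51.

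What did PCN, the reference activator of rodent PXR, change? Ces2c rose 7.75-fold (2.95 ± 0.35 log2, adjusted p = 1.29e-05) and Cyp3a23-3a1 6.99-fold (2.80 ± 0.27, adjusted p = 2.31e-07), n = 4 against 4, and both calls held in every alternative. Cyp2b1 rose 3.77-fold (1.92 ± 0.31, adjusted p = 0.00173) and also held. Cyp2b2 rose 2.40-fold (1.26 ± 0.24, adjusted p = 0.00998), lost with normexp (0.622, the highest over the alternatives), with the mean of its probes (0.490) and without PCN 1 (0.0707). Sult2a6 rose 10.8-fold (3.43 ± 0.68, adjusted p = 0.0210) and Cyp3a9 4.96-fold (2.31 ± 0.48, adjusted p = 0.0348), lost in 6 and 10 of 17 alternatives (up to 0.219 and 0.318, both with only the compared groups). Ces2a rose 6.28-fold (2.65 ± 0.26, adjusted p = 2.37e-07), Ugt2a3 5.09-fold (adjusted p = 0.000517) and the uptake transporter gene Slco1a4 4.10-fold (2.04 ± 0.31, adjusted p = 0.000517). Each was lost with only the compared groups in the fit (0.108, 0.318 and 0.137, the highest over the alternatives). Cda rose at least 4.59-fold (adjusted p = 0.000344, lost at 0.147 with only the compared groups and at 0.493 with normexp, the highest). Ugt2b1 rose 4.59-fold (adjusted p = 0.00641) and the sterol transporter gene Abcg8 5.53-fold (adjusted p = 0.00707). Ugt2b1 was lost without PXR control 3 (0.0640) or PCN 2 (0.0644) and with normexp (0.0576), Abcg8 without PXR control 1 (0.0692), PCN 1 (0.0698) or PCN 2 (0.0764), and the highest over the alternatives was 0.277 and 0.316. Taf15 was 1.79-fold lower (adjusted p = 0.000517) but above background on 1 of 4 PCN arrays, and with normexp its change was 0.23 (adjusted p = 0.661, the highest over the alternatives). Cyp3a2 (0.79), Abcc3 (1.28 ± 0.42), Gadd45b (1.87 ± 0.42, adjusted p = 0.0639), Por, Alas1, Cyp1a2, Cyp4a1 (0.01 ± 0.29), Cyp7a1, Ccnd1 and Mki67 did not pass. Gadd45b passed without PCN 3 (0.0170, the lowest over the alternatives).

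Of 19 PXR target genes 9 rose after PCN (12 rose and 1 fell over the list alone), median 1.12 log2, 1.08 with slide as a block (camera adjusted p = 4.57e-27). Of 22 CAR targets 6 rose (10 and 1), median 0.60 (camera adjusted p = 1.47e-16), and of 20 glucuronosyl- and sulfotransferases 6 (11), Ugt2a3 and Ugt2b1 among them, median 0.44 (camera adjusted p = 7.19e-14). Bile acid genes had 3 of 18 higher, with a median of -0.07, a mean of 0.08 and no camera call (adjusted p = 0.513). Glutathione transferases had a median of 0.26 with 0 of 18 past the threshold (camera adjusted p = 0.000313, 0.867 with normexp; adjusted p = 0.246 with an estimated correlation). Macrophage markers had a median of -0.47 (4 of 12 lower over the list alone, camera adjusted p = 9.26e-08; adjusted p = 0.246 with an estimated correlation) and immediate early genes -1.11 (camera adjusted p = 1.71e-05; adjusted p = 0.295 with an estimated correlation). PCN changed 28 genes, 26 higher and 2 lower (92.9% higher), 23 by at least 2-fold. The count was 15 without PXR control 1, PCN 1 or PCN 2, 19 with slide as a block and 5 with only the compared groups. Normexp moved the median of all genes to 0.12 log2. Within 3 slides Cyp3a23-3a1 rose by 2.09 to 3.06 log2 and Cyp2b1 by 1.64 to 2.36.

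What did DES, a synthetic oestrogen, change? By the number of genes this was the largest response. Stc2 rose at least 202-fold (adjusted p = 1.88e-17), Myom2 at least 317-fold and Pvalb at least 46-fold, all below background in controls, n = 3 against 4. Cited4 rose 408-fold (8.67 ± 0.49 log2), S100g, the vitamin D dependent calcium-binding protein gene, 189-fold (7.56 ± 0.49, adjusted p = 1.67e-13) and Rbp7 187-fold. Lifr, which encodes the leukaemia inhibitory factor receptor, rose 98.1-fold (6.62 ± 0.22, adjusted p = 4.58e-21, above background on 3 of 4 controls), Prlr 37.1-fold (5.21 ± 1.34), Orm1 18.9-fold, Bhlhe41 16.4-fold and Tff3 16-fold (adjusted p = 2.84e-10). Abcc3 rose 10.4-fold (3.39 ± 0.45). Akr1b7 rose by 10.86 ± 2.46 log2 (adjusted p = 0.000880), above background on 1 of 4 controls.

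DES lowered other genes strongly. Car3 (chromosome 2, 88109979 to 88110038), a male-biased carbonic anhydrase gene, was 703-fold lower (-9.46 ± 0.73, adjusted p = 1.07e-11) and above background on 1 of 3 DES arrays. Sult1e1, the oestrogen sulfotransferase gene, was 74.2-fold lower (-6.21 ± 0.57), above background on 2 of 3. The bile acid hydroxylase gene Cyp8b1 was 81.1-fold lower (-6.34 ± 0.43, adjusted p = 7.10e-13), the desaturase genes Fads2 and Fads1 31.7-fold and 28-fold lower, and the male-specific cytochrome gene Cyp2c11 19.8-fold lower (-4.31 ± 0.47, adjusted p = 2.57e-08). Abcg5 was 9.43-fold lower, Hmgcs1 9.13-fold, Cyp4a1 5.96-fold (-2.58 ± 0.31), Serpina6 5.32-fold, Gadd45b 5.05-fold, Cyp3a2 5.01-fold (-2.33 ± 0.34), Apoa2 4.41-fold and Cyp1a2 4.11-fold. Of the red cell genes, Hbb was 7.99-fold lower (adjusted p = 7.89e-05), Alas2 5.57-fold and Ahsp 5.54-fold. Alas1 was 2.92-fold lower (-1.55 ± 0.44, adjusted p = 0.00685), lost with slide as a block (0.0573, the highest over the alternatives). Cyp2b1 did not pass (-0.81 ± 0.34, adjusted p = 0.0629, range 0.000410 to 0.373), but without DES 3 it was at -1.46 (adjusted p = 0.000410), and it passed with quantile normalization (0.0423) and the mean of its probes (0.0232). Cyp2b2 (-0.66 ± 0.25, adjusted p = 0.0440) passed in the main setting but was lost in 12 of 16 alternatives. Ccnd1 (-1.37) did not pass, except with quantile normalization (0.0481), the mean of its probes (0.0414) or only the compared groups (0.00787, the lowest over the alternatives). Cyp3a23-3a1 (0.28 ± 0.29), Cyp3a9, Cyp7a1 (-0.99), Por and Mki67 (0.19 ± 0.42, with probes that differed in sign) did not pass.

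Of 17 male-biased genes 14 fell after DES and 0 rose, Cyp2c11, Sult1e1 and Mup5 among them (median -1.91 log2, -1.82 with slide as a block, camera adjusted p = 9.74e-11, 0.0187 with an estimated correlation). Of 18 bile acid genes 11 fell and 1 rose (12 and 1 over the list alone), Cyp8b1, Abcb4 and Slc10a1 among them, median -0.87 (camera adjusted p = 1.78e-05, 0.0187 with an estimated correlation). Of 31 PPARalpha targets 22 fell, with Ehhadh 6.75-fold and Hadha 1.98-fold lower, median -0.92 (camera adjusted p = 9.01e-08; adjusted p = 0.289 with an estimated correlation). Of 13 endothelial markers 9 rose and 1 fell, with Tie1, Stab2 and Lyve1 at 2.98, 2.73 and 2.31-fold, median 0.95 (camera adjusted p = 0.000236; adjusted p = 0.103 with an estimated correlation). Of 17 hepatocyte markers 10 fell (12), median -0.42 (camera adjusted p = 2.74e-05; adjusted p = 0.289 with an estimated correlation), and of 8 red cell markers 5 fell (6), median -2.12 (camera adjusted p = 0.0140; adjusted p = 0.743 with an estimated correlation).

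Other lists after DES had no camera call. Cholesterol synthesis had 3 of 25 higher and 10 lower (adjusted p = 0.175), CAR targets 7 of 22 and 5, PXR targets 1 of 19 and 8, female-biased genes 3 of 13 and 1, among them Prlr and Trim24 (9.31-fold higher), and oestrogen and growth hormone responsive genes 5 of 17 and 5. Acute phase genes had 1 of 21 higher and 8 lower, with a median of -0.34 and a mean of 0.10. Circadian genes had 1 of 16 higher and 3 lower (median -0.15, mean 0.25), p53 genes 3 of 17 and 4 (median 0.08, mean -0.36, adjusted p = 0.985) and fatty acid genes 5 of 20 and 3 (median 0.12, mean -0.24). Oncofetal genes had 1 of 11 higher and 2 lower, pancreas markers 1 of 5 and 1, and cholangiocyte markers 0 of 8 and 0. These last lists, and p53 and circadian genes, had no camera call after any compound.

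DES changed 6945 genes, 3290 higher and 3655 lower (47.4% higher, against 50.4% with quantile normalization), 2251 by at least 2-fold. With slide as a block the count was 6286. Normexp moved the median of all genes to 0.14 log2. Within 2 slides the male-biased list was at -1.85 to -1.69 log2, the bile acid list at -0.82 to -0.76 and the red cell list at -3.03 to -1.64.

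What did DIA, a benzodiazepine, change? Drug metabolism genes and dividing-cell genes rose together. Abcc3 rose 33.9-fold (5.08 ± 0.45 log2, adjusted p = 6.78e-09), Cyp2b1 29.9-fold (4.90 ± 0.34, adjusted p = 2.28e-11), Cyp2b2 14.4-fold, Ugt2b1 12.3-fold and Cyp3a23-3a1 4.16-fold (2.06 ± 0.29, adjusted p = 1.94e-05), n = 3 against 4. The aldo-keto reductase gene Akr1b8 rose 52.1-fold (5.70 ± 0.97), Akr7a3 6.28-fold, Ugt1a6 5.84-fold, Ephx1 5.11-fold, Nqo1 4.18-fold (2.06 ± 0.41) and Gstp1, a marker of altered liver foci, 3.14-fold (1.65 ± 0.18). The proliferation marker gene Mki67 (chromosome 1, 195310355 to 195313039) rose 3.92-fold (1.97 ± 0.42, adjusted p = 0.00193), Kif20a 5.83-fold, Mcm3 2.99-fold and Birc5 2.79-fold (1.48 ± 0.22). Elovl6, a fatty acid elongase gene, rose 3.60-fold. Tk1 rose 2.95-fold (adjusted p = 3.99e-05), lost with normexp (0.0552, the highest over the alternatives).

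Among the falls after DIA, Cyp2c11 was 4.46-fold lower (-2.16 ± 0.47, adjusted p = 0.00259), the aminotransferase gene Got1 3.41-fold (-1.77 ± 0.36, adjusted p = 0.00133), Sult1c3 2.57-fold and the muscle adaptor gene Stac3 39.2-fold (-5.29 ± 1.32, adjusted p = 0.00735). Nox4 was 6.86-fold lower, above background on 2 of 3 DIA arrays. Apoh (-0.50 ± 0.09, adjusted p = 0.000395) fell in the main setting but not with quantile normalization (0.171) or normexp (0.450, the highest over the alternatives), and Serpina3n (-0.73 ± 0.15, adjusted p = 0.00126) not with normexp (0.213, the highest). Cyp3a2 (-0.53), Cyp3a9, Cyp1a2 (0.01), Cyp4a1 (0.05 ± 0.31), Cyp7a1, Por (0.34), Alas1, Gadd45b and Ccnd1 (-1.57 ± 0.57) did not pass, Ccnd1 only with the compared groups alone (0.0156, the lowest over the alternatives).

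Of 36 cell cycle genes 30 rose after DIA and 0 fell (32 and 1 over the list alone), median 1.57 log2, 1.54 with slide as a block (camera adjusted p = 2.23e-29, 0.00243 with an estimated correlation). Of 22 CAR targets 14 rose, median 1.18, of 19 PXR targets 9 rose and 1 fell (9 and 2), median 0.77, of 20 NRF2 targets 12 rose (13), median 0.96, of 18 glutathione transferases 11, median 0.82, and of 20 glucuronosyl- and sulfotransferases 11 rose and 2 fell (12 and 2), median 0.59. All 5 camera calls held with an estimated correlation, the weakest for PXR targets (0.0346). Fatty acid synthesis had 4 of 20 higher (9), median 0.59 (camera adjusted p = 0.00228, 0.273 with an estimated correlation). Falls were in hepatocyte markers (8 of 17, 14 over the list alone, median -0.39, camera adjusted p = 7.92e-07; adjusted p = 0.0854 with an estimated correlation) and acute phase genes (7 of 21, 10, median -0.45, camera adjusted p = 0.000549, 0.0594 with normexp; adjusted p = 0.214 with an estimated correlation). Gluconeogenesis genes (5 of 20 lower, 7, median -0.51, camera adjusted p = 0.000814; adjusted p = 0.277 with an estimated correlation) and macrophage markers (4 of 12, 6, median -0.60, camera adjusted p = 0.00178; adjusted p = 0.376 with an estimated correlation) fell as well. Lymphocyte markers had 2 of 9 lower (3), median -0.67 (camera adjusted p = 0.0106, 0.328 with an estimated correlation).

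DIA changed 2725 genes, 930 higher and 1795 lower (34.1% higher, against 43.0% with quantile normalization and 48.8% with normexp before it), 764 by at least 2-fold. Without DIA 3 the count was 1433, and with slide as a block 2092. Normexp moved the median of all genes to -0.13 log2. Within 2 slides Cyp2b1 rose by 4.28 to 5.53 log2, the cell cycle list by 1.09 to 2.17 and the NRF2 list by 0.57 to 2.03.

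Did the control sets differ? They did, so compounds of different sets are compared only through their own controls. The glutathione synthesis gene Gclm was at least 7.87-fold higher in PXR than in CAR controls (adjusted p = 1.13e-10), Ergic2 at least 30.5-fold, Zfp36 at least 9.49-fold and Csad 39.1-fold (5.29 ± 0.66 log2, above background on 2 of 4 CAR controls), n = 4 against 4. Lower in PXR controls were Dact1 (6.67-fold, -2.74 ± 0.65), Inpp4b (6.11-fold), Eng (-1.10 ± 0.14, adjusted p = 1.42e-07), B2m (-0.96 ± 0.12) and Rbp4 (-0.99 ± 0.09, adjusted p = 6.54e-10). Alb was lower by the main scaling (-0.87 ± 0.11, adjusted p = 2.80e-07) but at 0.03 after quantile normalization (adjusted p = 0.809, the highest over the alternatives), and Ambp went from -0.79 ± 0.10 to 0.18 (adjusted p = 0.0412). C3 went from -0.95 ± 0.10 to -0.03 (adjusted p = 0.781).

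In all 9063 genes differed, 3715 higher and 5348 lower in PXR controls (41.0% higher, against 49.8% with quantile normalization), 2247 by at least 2-fold, of which 1294 were higher and 953 lower. The median of all genes was -0.12 log2, -0.03 with quantile normalization and -0.18 with normexp. Of 17 hepatocyte markers 13 were lower and 1 higher, median -0.59 (camera adjusted p = 0.00480, 0.422 with quantile normalization and 0.259 with normexp; adjusted p = 0.913 with an estimated correlation), of 21 acute phase genes 9 lower, median -0.44 (camera adjusted p = 0.0451, 0.804 and 0.281; adjusted p = 0.913 with an estimated correlation), and of 13 endothelial markers 8 lower, median -0.66 (camera adjusted p = 0.0265, 0.0718 and 0.246; adjusted p = 0.913 with an estimated correlation). No slide held both sets, so slide entered only as a random block, which gave 9093 genes.

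Did PHE and PB differ? Both are anticonvulsants with a phenyl-substituted ring holding a urea unit, PB a barbiturate and PHE a hydantoin, and they were given at different doses (225 and 75 mg/kg/day). PHE minus PB was 0.06 log2 for Cyp2b1 (95% interval -0.57 to 0.70; named outside the naming rule), -0.02 for Cyp2b2 (-0.50 to 0.46), 0.34 for Cyp3a23-3a1 (-0.21 to 0.88), -0.30 for Abcc3 (-1.16 to 0.55), 0.20 for Ugt2b1 (-0.61 to 1.00), 0.36 for Ces2c (-0.36 to 1.08) and 0.23 for Ephx1 (-0.26 to 0.72), n = 4 against 4. For Mgst2 (0.42, 0.14 to 0.71), Gsr (0.47, 0.09 to 0.85) and Gadd45b (-1.28, -2.14 to -0.42) the interval left out 0, with adjusted p = 0.347, 0.432 and 0.347, and for Grin2c, outside the rule, it was wide (0.85, -0.11 to 1.82). Cyp3a18 (1.53 ± 0.37), Ugt2a3 (1.30 ± 0.35) and Slco1a4 (1.00 ± 0.31) had no overlap between the arrays of PHE and PB, with adjusted p = 0.156, 0.223 and 0.306. Of 21275 genes 18226 (85.7%) had a 95% interval within 1 log2 of zero on both sides, with a median width of 0.38 to each side. Among 963 genes changed by PB or PHE this held for 823 (85.5%).

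Cyp4a1 was 3.10-fold lower after PHE than after PB (-1.63 ± 0.29, interval -2.22 to -1.05, adjusted p = 0.0225, range over alternatives 0.00274 to 1.00). That call was lost with normexp (1.00), with only the compared groups (0.437), with slide as a block (0.158) and with rat number as a block (0.129). It was also lost without PB 1 (0.0533), PB 4 (0.275), PB 5 (0.104), PHE 3 (0.124) or PHE 4 (0.151). Acaca (0.80 ± 0.15, adjusted p = 0.0588), Eci1 (-0.88 ± 0.18), Ehhadh (-1.25 ± 0.28), Acot2 (-1.36 ± 0.31), Fasn (1.37 ± 0.45), Ube2c (-1.81 ± 0.39), Cdk1 (-1.75 ± 0.39) and Top2a (-1.76 ± 0.40) did not pass in the main setting. Without PHE 1 Acaca and Eci1 passed (0.00175 each; Acaca also at 0.0272 with trended variances), Ehhadh (0.0324) and Acot2 (0.0431) as well.

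In all 3 genes differed between PHE and PB, 1 higher and 2 lower, the others being expressed sequence tags without a symbol. The count was 14 without PHE 1, 5 without PHE 4, 1 without PB 4, and 1 with slide as a block. Over lists, PPARalpha targets had a median of -0.41 with 1 of 31 lower (1 higher and 18 lower over the list alone), camera adjusted p = 3.40e-16 (adjusted p = 0.0729 with an estimated correlation). Cell cycle genes had -0.53 with 0 of 36 past the threshold (18 lower), camera adjusted p = 8.87e-16 (0.0729 with an estimated correlation). Cholesterol synthesis had 0.46 (camera adjusted p = 8.36e-07, 0.311 with an estimated correlation) and fatty acid synthesis 0.43 (camera adjusted p = 1.20e-05, 0.174 with an estimated correlation). CAR targets (0.02, adjusted p = 0.761) and PXR targets (0.34, adjusted p = 0.0575) had no camera call.

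How did the CAR activators (PB, DDE and PHE) differ from the PXR activators (CLO and PCN)? The mean effect on the 2B cytochromes was larger in the CAR activators: Cyp2b12 by 4.73 ± 0.28 log2 (26.6-fold, adjusted p = 4.97e-13), Cyp2b1 by 3.76 ± 0.37 (13.5-fold), Cyp2b15 by 3.61 ± 0.28, Cyp2b2 by 3.30 ± 0.28 (9.87-fold) and Cyp2b21 by 2.06 ± 0.21, with Ephx1 at 1.71 ± 0.29 (3.28-fold, adjusted p = 0.00305), n = 12 against 8 treated arrays, each against its own 4 controls. Abcc3 (2.69 ± 0.50, adjusted p = 0.0106) passed but not without CAR control 3 (0.0579), PXR control 2 (0.0553) or PXR control 4 (0.0536), nor with only the compared groups (0.0685) or the mean of its probes (0.0646), and normexp gave 1.00, the highest over the alternatives. Aldh1a1 (2.59-fold, adjusted p = 0.00234) was lost with normexp (0.707, the highest). Ugt2a1 passed with a lower effect in the CAR activators (adjusted p = 0.0193), but it was above background on 0 of 4 controls of either set, so the size of this difference was not measured, and the call was lost without CAR control 3 (0.0910) or 4 (0.0536), PXR control 3 (0.0563) or 4 (0.0706) and with normexp (1.00, the highest). For Cyp3a23-3a1, named outside the rule, the adjusted p was 0.785 or higher in every alternative.

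Of 22 CAR target genes 5 were more strongly raised by the CAR activators (15 over the list alone), median 1.05, 1.11 with slide as a block (camera adjusted p = 3.97e-19). Of 19 PXR targets 3 were (5, and 1 less), median 0.31 (camera adjusted p = 5.35e-05, 0.173 with an estimated correlation). The CAR and PXR lists share genes such as Cyp2b1 and Ces2c, so they are not separate evidence. Glutathione transferases had 0 of 18 (6), median 0.27 (camera adjusted p = 8.06e-07, 0.0632 with an estimated correlation). In all 18 genes differed, 17 higher and 1 lower, 14 by at least 2-fold. The count was 34 without CLO 4, 12 without DDE among the CAR activators, and 18 with slide as a block.

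Which genes did all 5 activators change? All 8 such genes rose: Cyp2b1 (mean 5.78 log2), Cyp2b2 (4.70), LOC498152 (4.55), Ugt2b1 (3.79), Ces2c (3.77), Ces2a (2.83), Cyp3a23-3a1 (2.69) and Aldh1a1 (2.03). Each group had n = 4. Independent lists of the same sizes share 7.28e-07 higher genes. Without PCN 2 the count was 5, and with slide as a block 7. The same 8 rose after DIA. PB, DDE and PHE shared 97 higher and 9 lower genes, CLO and PCN 11 higher and 0 lower, and PB, DDE, PHE, CLO and DIA 35 higher and 0 lower. Of the 146 genes changed by PB, 93.8% had the same sign after CLO, 91.8% after DIA, 84.9% after PCN and 69.2% after DES, which have another control group.

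How alike were the responses across all genes? Compounds that share a control share its noise, so r is given beside that of simulated unchanged groups. Across genes, which are not independent replicates, r was 0.737 for PB and DDE, 0.719 for DDE and PHE and 0.636 for PB and PHE, and simulated unchanged groups of the CAR set had a mean of 0.484 (0.0338 to 0.780). With the 4 controls split between the compounds, r was 0.393 (0.270 to 0.469), 0.429 and 0.291. The covariances were 0.107, 0.127 and 0.0850 against 0.0388 simulated, and 0.0709, 0.0909 and 0.0490 after the split. PB and DDE shared 114 higher and 17 lower genes, DDE and PHE 439 and 127, and PB and PHE 98 and 9, with 0 in opposite directions, where independent lists share 6.34, 37.3 and 3.93 in the same direction. After the split they shared 50.7, 134 and 43.8 on average. CLO and PCN had r = 0.572, covariance 0.0589, against 0.492 and 0.0353 simulated and 0.245 after the split, and DES and DIA 0.462, covariance 0.196, against 0.421 and 0.0354 and 0.372 after the split. CLO and DIA had 0.534, 0.330 after the split, against 0.429 simulated. An r above the simulated or split value is not by itself a shared effect.

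Pairs across the sets share no control. Among these 16, r ran from 0.0478 for DIC and DIA to 0.495 for PB and CLO, and among the 12 pairs with a shared control from 0.241 for DDE and DIC to 0.737. DDE and DIA had 0.406 and shared 263 higher and 159 lower genes (90.6 in the same direction for independent lists) with 8 in opposite directions (108.7), and PB and DIA 0.384 with 75 higher, 11 lower and 1 opposite. DIC and DIA shared 56 higher and 139 lower genes (100.3 in the same direction for independent lists) and moved 143 in opposite directions (115.8).

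**Figure D4:**
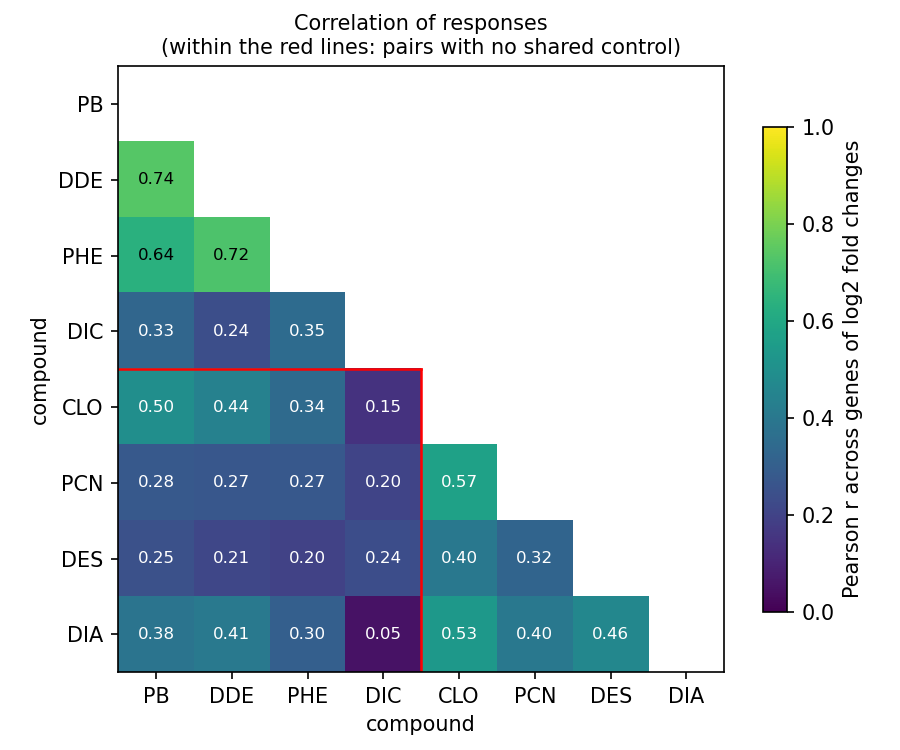
Pearson correlation across genes of the log2 changes of each pair of compounds, with red lines around the pairs that share no control. Outside the lines r reaches 0.737 (PB and DDE), inside 0.495 (PB and CLO).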

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

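The rule that set single arrays apart, and all explanations weighed below, were chosen after the results were seen. The relabelling tests, in which arrays are exchanged between the compared groups, were chosen before.

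In the relabelling tests the real grouping is counted with the others, and the result says only whether chance can be excluded. Of 35 groupings, 1 gave as many changed genes as the real one, namely the real one itself, for PB (146 genes, at most 5 in any other), DDE (1556, 7), PHE (924, 3), DIC (1687, 6), CLO (114, 2), PCN (28, 1), DES (6945, 3944), DIA (2725, 702) and the control sets (9063, 17). For DES and DIA the other groupings with many genes were those with 3 PXR controls against the rest. For PHE against PB 2 of 35 groupings gave as many genes as the real one (3), the highest 31, so chance is not excluded. That highest grouping set PHE 1, PHE 3, PB 1 and PB 3 against the rest and follows the slides. For the CAR and PXR activators 2 of 100 relabellings gave at least the real count (18, highest 21), and for the genes changed by all 5 activators 1 of 100 (8, highest other 0).

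First pattern: the control sets differ in 9063 genes. After quantile normalization 8810 genes differed, which argues against the overall scaling of the arrays as the whole cause. Of 2 scan days 0 held both control groups, and of the extraction software versions 0 did, so a difference between animals and a difference in scanning or software cannot be told apart. Whether effects against the own set's control depend on the cause was not tested.

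Second pattern: markers of other cell types move after DIC. A lower share of hepatocytes would raise all other lists about alike. The stellate list was at -0.092 log2 (within slides -0.34 to 0.014) and the red cell list at 1.02 (0.36 to 2.15). These are the lowest and highest of 7 lists, so their gap cannot decide this. Hepatocyte markers, at 0.19 (0.22 to 0.23), give no sign of a lower share. More blood left in the liver remains open, and more red cell precursors could raise the same genes.

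Last pattern: 30 cell cycle genes rose after DIA. The list median was 1.58 log2 with quantile normalization, which argues against the overall scaling. Its lowest value without any 1 array was 1.32, which argues against 1 array as the cause. Macrophage markers (-0.60, within slides -1.26 to -0.38) and lymphocyte markers (-0.67, -1.63 to -0.30) were below 0, which gives no sign of more of these cells. Neutrophil and monocyte markers were at -0.13 (-0.92 to 0.53). Dividing leukocytes remain open, since that last list spans 0 and marker levels do not show whether the cells present divide.

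Arrays apart from the others of their group were looked for in 512 combinations of named gene and group of 4 arrays, by the gap to the next array over the range (Dixon's ratio, which sets apart about 1 in 20 groups of unremarkable arrays), and 26 were found. Levels are log2 signal over the array's 75th percentile, with the others in brackets.

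In CAR controls, control 1 stood apart for Alox15 at -1.42 (-1.77 to -1.75) and Hsd11b2 at 2.15 (1.34 to 1.37), control 3 for Acadm at 7.03 (7.12 to 7.13), control 4 for Rfx2 at -3.25 (-2.05 to -1.87) and control 5 for Cyp2b1 at 2.86 (3.12 to 3.15). PB 1 was high for Rnase4 at 6.70 (6.14 to 6.22). PHE 1 was low for Ephx1 at 7.25 (7.63 to 7.70). PHE 4 was low for Mki67 at -4.03 (-2.33 to -2.28), Slc34a2 at -4.59 (-3.13 to -2.99) and Top2a at -5.43 (-3.96 to -3.73). DIC 5 was high for Ltc4s at 1.58 (0.97 to 0.99) and low for Orm1 at 8.06 (9.15 to 9.30).

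In the PXR set, PXR control 1 had 5: Ces2c at 0.043 (0.76 to 0.86), Elovl6 at -1.45 (-1.10 to -1.04), Esr1 at -4.01 (-3.33 to -3.20), Hspa8-ps5 at -1.74 (highest other -0.87) and Trim24 at -2.09 (-1.09 to -0.93). PXR control 2 was low for Aldh1a7 at -5.98 (-0.81 to -0.36) and Slc10a1 at 6.94 (7.07 to 7.09). PXR control 3 was high for Cyp4a1 at 7.20 (6.41 to 6.52) and Dact1 at -2.17 (-2.96 to -2.83), and PXR control 4 low for Clock at -4.63 (-3.99 to -3.88). CLO 1 was low for Gsr at 0.63 (1.14 to 1.23) and CLO 2 high for Mki67 at -1.32 (-1.79 to -1.75). PCN 2 was high for Grin2c at -1.77 (-2.43 to -2.36) and PCN 4 low for Cyp2b15 at 2.84 (3.41 to 3.52).

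The effects of the CAR and PXR activators differed in 18 genes, listed because a response differs between groups: Cyp2b12 (4.73), Cyp2b1 (3.76), Cyp2b15 (3.61), Cyp2b2 (3.30), Grin2c (2.72), Abcc3 (2.69), Cyp2b21 (2.06), Ephx1 (1.71), Ugt2a1 (-2.47) and Aldh1a1 (1.37) are those the naming rule gives. The call of Grin2c (adjusted p = 0.0418, range over alternatives 0.0152 to 1.00) was lost with normexp (1.00), without the filter (0.0784), with slide as a block (0.0869) and without any 1 of the CAR controls (1: 0.109, 3: 0.104, 4: 0.0833, 5: 0.0616). It was also lost without PB 3 (0.0646), PB 5 (0.0671), DDE 4 (0.0632), PHE 2 (0.0643), PHE 4 (0.0614), PXR control 2 (0.177), 3 (0.0712) or 4 (0.113), CLO 1 (0.0728) or 3 (0.0848), or PCN 1 (0.0617), 3 (0.0709) or 4 (0.0634). The fitted value of Ugt2a1 is no measured size. Limits of the Abcc3, Ugt2a1 and Aldh1a1 calls are given with the comparison.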

How the results depend on the processing

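All alternatives but normexp then quantile normalization were chosen before the results were seen. Where an alternative changed a result, the cause was not tested, except where the alternative's own construction gives it (a stricter threshold gives fewer genes).

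With normexp the residuals shared 1 component holding 60.5% of the variance, against 11.2% in the main setting, and counts fell to 36 for PB, 218 for DDE, 76 for PHE, 142 for DIC, 39 for CLO, 9 for PCN, 2848 for DES, 635 for DIA, 3734 for the control sets, 0 for PHE against PB, 6 for the CAR and PXR activators and 4 for all 5 activators. Ccne2 after PHE (0.29 log2), Taf15 after PCN (0.23) and Esr1 after DES (0.18) reversed. So did lists after PCN (PPARalpha targets, adjusted p = 0.00206, acute phase 0.152, glutathione transferases 0.867, hepatocyte markers 0.000661) and after PHE (acute phase 0.0141, cell cycle 0.177, male-biased genes 0.0344, reference genes 0.370). Correlations became 0.838 for PB and PHE, 0.622 PB and PCN, 0.448 PB and DES, 0.215 PB and DIA, 0.381 DDE and PCN, 0.301 DDE and DES, 0.634 PHE and PCN, 0.435 PHE and DES, 0.109 PHE and DIA, 0.310 DIC and PCN, 0.336 DIC and DES, -0.00463 DIC and DIA (reversed), 0.495 PCN and DES, 0.0290 PCN and DIA and 0.301 DES and DIA. With quantile normalization added after normexp, CLO had 194 genes and PHE against PB 1.

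Without the filter on dim probes counts were 80 for PB, 1025 for DDE, 448 for PHE, 995 for DIC, 66 for CLO and 13856 for the control sets. Correlations were 0.657 for PB and DDE, 0.241 PB and CLO, 0.0258 PB and PCN, 0.172 PB and DES, 0.270 PB and DIA, 0.649 DDE and PHE, 0.249 DDE and CLO, 0.0533 DDE and PCN, 0.316 DDE and DIA, 0.179 PHE and CLO, 0.0746 PHE and PCN, 0.221 PHE and DIA, 0.0601 DIC and CLO, 0.0937 DIC and PCN, 0.153 DIC and DES and -0.0141 DIC and DIA (reversed). Signal over background limits what can be said of dim genes: where 0 arrays of a group were above background a smaller fold is printed as "at least", and where only some were, the fitted fold rests partly on values near background.

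With only the compared groups in the fit, counts were 51 for PB, 269 for DDE, 190 for PHE, 707 for DIC, 57 for CLO, 5 for PCN, 0 for PHE against PB and 5 for all 5 activators. Against the other set's control they were 9740 for PB, 10011 for DDE, 10351 for PHE, 11604 for DIC, 9845 for CLO, 9624 for PCN, 11865 for DES and 11445 for DIA. Against the mean of both controls they were 5134 for PB, 6650 for DDE, 6799 for PHE, 8517 for DIC, 5355 for CLO, 4799 for PCN and 8787 for DIA, since these carry the difference between the control sets.

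At an adjusted p of 0.01 counts were 56 for PB, 606 for DDE, 253 for PHE, 481 for DIC, 45 for CLO, 16 for PCN, 1244 for DIA and 1 for PHE against PB. With a minimum of 2-fold they were 72 for PB, 339 for DDE, 180 for PHE, 324 for DIC, 61 for CLO, 2251 for DES, 764 for DIA and 2247 for the control sets. The CAR and PXR activators differed in 28 genes with trended and robust variances and in 82 with all 4 compounds of each set. Quantile normalization reversed Alb (0.029) and Ambp (0.18) and the acute phase (adjusted p = 0.804) and hepatocyte lists (0.422) between the control sets. Of 352 list tests 129 passed with the preset correlation and 35 with an estimated one.

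With slide as a block the counts were 108 for PB, 1588 for DDE, 1258 for PHE, 1595 for DIC, 83 for CLO, 19 for PCN, 6286 for DES, 2092 for DIA, 1 for PHE against PB and 18 for the CAR and PXR activators. With rat number as a block they were 134, 1626, 1036, 1514, 108, 29, 7116, 2953, 1 and 22. The authors' values give no comparison of the control sets.

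Leaving out each array in turn gave 74 to 111 genes for PB, 603 to 1899 for DDE, 348 to 908 for PHE, 771 to 1702 for DIC, 59 to 113 for CLO, 15 to 35 for PCN, 5580 to 6450 for DES, 1433 to 2377 for DIA, 8031 to 8614 for the control sets, 1 to 14 for PHE against PB, 13 to 34 for the CAR and PXR activators and 5 to 9 for all 5 activators. The correlations ran over 0.664 to 0.766 (PB and DDE), 0.588 to 0.684 (PB and PHE), 0.275 to 0.436 (PB and DIC), 0.432 to 0.526 (PB and CLO), 0.190 to 0.331 (PB and PCN), 0.186 to 0.277 (PB and DES), 0.324 to 0.439 (PB and DIA), 0.668 to 0.747 (DDE and PHE), 0.201 to 0.315 (DDE and DIC). Further pairs had 0.397 to 0.472 (DDE and CLO), 0.222 to 0.294 (DDE and PCN), 0.171 to 0.237 (DDE and DES), 0.360 to 0.426 (DDE and DIA), 0.290 to 0.423 (PHE and DIC), 0.281 to 0.391 (PHE and CLO), 0.205 to 0.318 (PHE and PCN), 0.163 to 0.220 (PHE and DES), 0.244 to 0.323 (PHE and DIA), 0.0854 to 0.180 (DIC and CLO), and the others 0.135 to 0.251 (DIC and PCN), 0.223 to 0.248 (DIC and DES), -0.00749 to 0.110 (DIC and DIA), 0.468 to 0.627 (CLO and PCN), 0.310 to 0.437 (CLO and DES), 0.445 to 0.605 (CLO and DIA), 0.260 to 0.359 (PCN and DES), 0.314 to 0.447 (PCN and DIA), 0.407 to 0.484 (DES and DIA). Without DIA 4 the correlation of DIC and DIA reversed (-0.00749).

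Of the 379 named gene results, 359 (all those covered) stayed the same with the authors' values (nearly the main levels minus a constant per gene and set, so no test), 374 with trended and robust variances, 368 with the mean of probes, 364 with quantile normalization, 371 with rat number and 349 with slide as a block, 350 without the filter, 311 with only the compared groups and 283 with normexp, where 93 were weaker. Of the 352 list tests 326 stayed the same with quantile normalization, 314 with the authors' values (which lack the control sets), 343 with rat number as a block, 279 with normexp and 258 with an estimated correlation, where 94 were weaker.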

Other observations

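Some genes moved after more than 1 compound in ways not described above. Stac3 was 336-fold lower after DES (-8.39 ± 1.32 log2, adjusted p = 9.56e-06, n = 3 against 4, above background on 2 of 3 DES arrays), besides its fall after DIA. After DIC it was 24.6-fold lower (-4.62 ± 1.22, adjusted p = 0.0189, range over alternatives 0.0111 to 0.0832), a call lost without CAR control 3 (0.0519), DIC 3 (0.0832) or DIC 5 (0.0611). Orm1 rose after both DIC (3.07 ± 0.28) and DES (4.24 ± 0.35), as did the endothelial genes Stab2 and Tie1. Whether these effects differ in size between compounds was not tested. Abcc3 rose after PB, DDE, PHE, CLO, DIA and DES, and for DES without a call for Cyp2b1 or Cyp3a23-3a1.

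After DES the kallikrein genes Klk1c9 and Klk1c2 rose at least 39.1-fold and 37.7-fold, and Arhgef28 246-fold (7.94 ± 0.40, adjusted p = 2.83e-16, above background on 1 of 4 controls). The transporter gene Ust5r was 24.5-fold lower (-4.62 ± 0.34, adjusted p = 3.51e-12), Akr1c2 33.4-fold lower (-5.06 ± 1.21, adjusted p = 0.00148), the bile acid uptake transporter gene Slc10a1 2.51-fold lower and the phospholipid transporter gene Abcb4 3.02-fold lower. DIA raised Ugt2b7 11.7-fold (3.54 ± 0.72, adjusted p = 0.00126, above background on 3 of 4 controls), Gsta3 2.72-fold and Mgst2 2.06-fold (1.04 ± 0.15). Between the control sets, Fcgr2b (-0.87 ± 0.12, adjusted p = 5.15e-07) was lower and the reference gene Ywhaz (0.73 ± 0.11, adjusted p = 4.30e-06) higher in PXR controls.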
